A study of Acinetobacter baumannii with 2 samples.

How the data were processed

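RNA was sequenced from *Acinetobacter baumannii* strain MTCC 9829 in 2 libraries, 1 labelled untreated and 1 labelled as treated with Sono-Fenton. Per the labels' protocols, cultures in nutrient broth were kept at 37 °C and shaken at 130 rpm, then collected in log phase, washed in saline and exposed to Sono-Fenton for 90 minutes. The same protocol states that the treated sample was grown again in nutrient broth to log phase before RNA was extracted. The treated library therefore holds RNA of regrown cells, not RNA taken at the end of the exposure. The protocol text is identical for both samples and does not say whether the untreated bacteria were washed, held in the reaction mixture or regrown. RNA was extracted with TRIzol and ribosomal RNA was depleted with the QIAseq FastSelect bacterial kit, per the labels' protocols.

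The authors deposited 1 table of raw read counts per gene for each library, with 3727 protein-coding genes and no rows for ribosomal RNA. Per the submitters' processing notes, the tools used were bcl2fastq 2.19.0.316, FastQC 0.11.9, MultiQC 1.9, fastp 0.20.1, Bowtie2 and featureCounts, the last 2 with no version. The genome build, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart. Where multi-mapping reads are dropped or shared out, the counts of near-identical gene copies are uncertain, which concerns genes whose names carry a copy number (such as antA_1). Gene identifiers, symbols and product names are those of the deposited tables, where 1961 genes have a symbol and 1652 are annotated as hypothetical proteins. The tables give no coordinates, so genes are placed only by the order of their locus tags. No genome was used here. A gene table of another strain of the species shared 0 of the 3727 identifiers and was not used for names, lengths or positions.

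The deposited counts summed to 22644432 in the untreated library and 26604691 in the treated library. Counts were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 0.944 for the untreated and 1.06 for the treated library. For each gene, the ratio of scaled counts (treated over untreated) was computed with a pseudocount of 0.5, with an exact conditional (Clopper-Pearson) 95% interval. With 1 library per group there is no replicate, so no test between conditions was possible, no p-value is given, and no difference has a replicate check. The intervals cover counting error only, and reads amplified by PCR without molecular identifiers are not independent molecules. The median width of the interval to either side was 0.73 (log2) for genes with 10 to 100 counts summed over both libraries, 0.27 for 100 to 1000, 0.11 for 1000 to 10000, and 0.04 above that. Of the genes, 3725 had at least 10 summed counts and were kept. A gene is called higher or lower in the treated library where its log2 ratio was at least 1 in size and its interval excluded 0. This is a rule of size, not a test of significance.

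Before the data were examined, 35 gene lists, the size rule and the rule for named genes were fixed. The lists were oxidative stress defence, siderophores, TonB-dependent receptors, iron storage and ferrous uptake, iron-sulfur cluster assembly, DNA repair and SOS, chaperones and proteases, drug efflux, beta-lactamases and drug-modifying enzymes, porins, capsule, lipooligosaccharide and lipid transport, type IV pili, chaperone-usher pili, type VI secretion, quorum sensing and ribosomal proteins. The others were ATP synthase, respiratory chain, the tricarboxylic acid and glyoxylate cycles, phenylacetate degradation, other aromatic compound degradation, fatty acid degradation, fatty acid synthesis, sulfur assimilation, branched-chain amino acid synthesis, histidine and arginine catabolism, compatible solutes, general stress proteins, toxin-antitoxin systems, mobile elements, prophage genes, two-component systems, cell division and peptidoglycan, and purine and pyrimidine synthesis. Members were found by symbol or product name, and 55 matches whose annotated product did not belong to the list were removed by name before list values were computed. Some members with another annotated role stayed, such as the transcription factor gene dksA among chaperones and proteases. For each list with at least 5 genes, the median log2 ratio was placed as a percentile among medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Percentiles up to 2.5 or from 97.5 are called outside the central 95%. They describe these 2 libraries, and list members that lie side by side in the genome are not independent.

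The named genes are the 12 highest and 12 lowest by the interval bound nearest to 0 among genes not annotated as hypothetical, uncharacterised or DUF proteins, up to 4 members per list by the same ranking, and a fixed set of stress, iron, envelope and reference genes. Of that set, katA, katX, sodC, dps, umuD, basD, ompA, carO, adeB, adeJ, adeG, abaI, csuA/B and rpoS are not used as symbols in the tables. Omp38 was found by product name. The symbol bauA is given there to a beta-alanine aminotransferase, not to the siderophore receptor it was fixed for, and was not used.

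Alternatives were total-count scaling, the size factors of DESeq2 1.42.0, no count minimum or a minimum of 100, a whole interval beyond 2-fold, a log2 ratio of at least 2, a pseudocount of 5, unmatched random lists and members by symbol alone. Circular shifts of each list along the locus-tag order and lists without the removals by name were added after seeing the data. The procedure was tested on simulated counts for the same 3725 genes, drawn with counting error alone from the pooled profile of both libraries. Of 50 genes each given a fold of 3, 6 or 10, 100% were called in the right direction. Of 50 genes given a fold of 1.5, which is below the rule, 0 were called. Of 3525 unchanged genes 0 were called, and 95.6% of their intervals held the true value. The simulation holds no variation between cultures, so it gives no rate of false calls for single cultures. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.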

Results

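Transcript levels were measured by RNA sequencing after ribosomal RNA depletion in *Acinetobacter baumannii* MTCC 9829, a strain of an opportunistic Gram-negative pathogen. The design has 1 untreated library and 1 library from bacteria exposed for 90 minutes to Sono-Fenton, a combination of ultrasound with the Fenton reaction, in which iron and hydrogen peroxide form hydroxyl radicals. The treated bacteria had been regrown to log phase before RNA extraction, per the labels' protocols. The untreated library held 22644432 counts with a median of 1032 per gene, and the treated library held 26604691 counts with a median of 1568 per gene. Counts were found for 3726 of the 3727 genes in each library, and 1 gene had 0 counts in both. The 100 genes with the most counts took 44.8% of the untreated and 40.2% of the treated library. Values are ratios of TMM-scaled counts between single libraries, and the ranges in brackets are 95% counting intervals.

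The comparison asks which genes differed in level between bacteria regrown after Sono-Fenton and untreated bacteria. Several enzymes of aromatic compound breakdown had far higher levels in the treated library. The anthranilate dioxygenase large subunit gene antA_1 (CAHBGAOC_01615) was 16.7-fold higher (14.2 to 19.9), with 149 counts in the untreated and 3293 in the treated library. The muconolactone isomerase gene catC (CAHBGAOC_01631) was 17.4-fold higher (13.9 to 22.2). The genes cbdA and cbdB, annotated as halobenzoate dioxygenase subunits, were 14.6-fold and 8.50-fold higher, and benC beside them was 8.02-fold higher. The highest ratio of a named gene was that of gatA_2 (CAHBGAOC_01611), annotated as an amidotransferase subunit, at 48.9-fold (38.1 to 64.9), from 59 counts to 3837. It lies in the same stretch of locus tags as antA_1, fabG_2 at 20.3-fold higher and the reductase gene yeaX at 8.72-fold higher. The transporter gene nanT_1 (9.24-fold), the dihydrolipoyl dehydrogenase gene CAHBGAOC_01821 (8.78-fold), pdhC beside it (8.34-fold) and smtB (8.70-fold) complete the 12 highest.

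The genes with the lowest ratios included enzymes and transporters for putrescine, 4-aminobutyrate, proline and lactate. The 4-aminobutyrate aminotransferase gene puuE (CAHBGAOC_00208) was 43.8-fold lower in the treated library (41.0 to 47.0), with 29032 counts against 873. The 4-aminobutyrate permease gene gabP_1 was 29.5-fold lower, and gabD_1, which carries the name of a succinate semialdehyde dehydrogenase, was 10.6-fold lower. The putrescine importer gene puuP was 21.0-fold lower, the gamma-aminobutyraldehyde dehydrogenase gene prr 19.1-fold lower (18.6 to 19.6) and the gamma-glutamylputrescine oxidoreductase gene puuB 11.1-fold lower. The proline catabolic gene putA (CAHBGAOC_01975) was 20.2-fold lower (19.6 to 20.9), with 65103 counts against 4243. The D-lactate dehydrogenase gene dld, the L-lactate permease gene lldP and lldR, in one stretch of locus tags, were 5.89-fold, 5.69-fold and 10.6-fold lower. The 12 lowest also held accA1_2 at 7.86-fold lower and its neighbour, the enoyl-CoA hydratase gene dpgD at 6.03-fold lower.

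**Figure D1:**
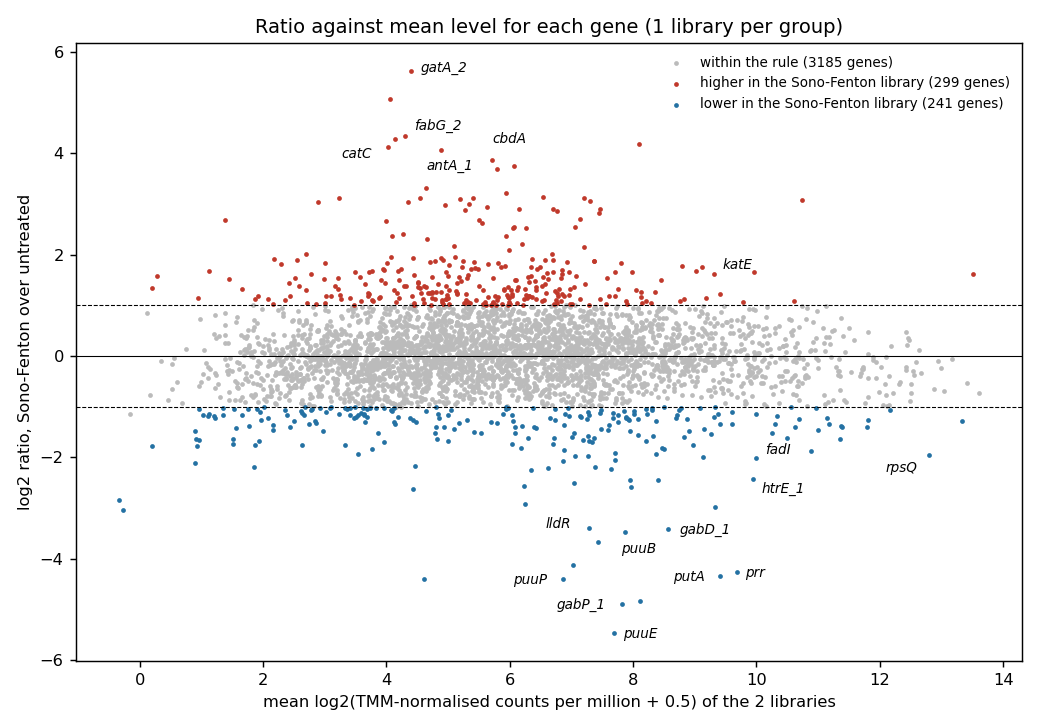
Each point is a gene, placed by its mean log2 level over the 2 libraries (x axis, log2 of the TMM-normalised count rate) and its log2 ratio of Sono-Fenton over untreated (y axis). Red points are the 299 genes called higher, blue points the 241 called lower, dashed lines the 2-fold bounds, and genes with the lowest ratios, such as puuE at -5.45, reach about as far from 0 as gatA_2 at 5.61.

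Of 3725 genes, 299 (8.03%) were higher and 241 (6.47%) were lower in the treated library by at least 2-fold, and 3185 were within the rule. Ratios of at least 4-fold were found for 50 higher and 33 lower genes. Hypothetical proteins made up 135 of the higher and 136 of the lower genes. Higher genes were 55.4% of the genes past the rule. With total-count scaling every log2 ratio moved by 0.17, and the split was 456 higher against 163 lower, or 73.7% higher. The 299 higher genes were all among the 456, and the 163 lower genes were all among the 241. Levels of single genes in the 2 libraries correlated at Pearson r = 0.947 across genes, which are not independent replicates. Differences near 2-fold, and the direction of any gene or list median between -0.17 and 0, thus rest on the scaling. With total-count scaling 8 named genes called lower were within 2-fold, namely atpC, lptE, mrkD_1, paaG, rcsC_1, soxR_1, umuC_2 and CAHBGAOC_03342, and with DESeq2 size factors kdsC was.

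Among carbon source genes, the list of aromatic compound degradation other than phenylacetate stood apart most. Of its 41 genes, 21 were higher and 1 was lower, with a median log2 ratio of 1.06, above all matched random lists (percentile 100). Phenylacetate genes did not share this. Of 17, 1 was higher (paaF_2) and 3 were lower, with a median of -0.18 (percentile 12.9). The epoxidase subunit gene paaE was 3.36-fold lower and paaZ 2.63-fold lower. Fatty acid degradation had a median of -0.48 over 18 genes (percentile 0.21), with 2 higher and 2 lower. The thiolase gene fadI was 4.04-fold lower (3.96 to 4.11), while the neighbours echA8_2 and fadJ_2 were 3.63-fold and 3.01-fold higher. These neighbours lie in a stretch of higher genes with mmsB and mmsA, names of valine catabolism, and may not serve fatty acid degradation. Fatty acid synthesis had a median of 0.47 over 19 genes (percentile 99.4), with 4 higher and 1 lower. The enoyl reductase gene fabI was 3.30-fold higher and the carboxylase gene accA 2.45-fold higher, whereas fabB_2 was 2.34-fold lower. The highest member, fabG_2, belongs to a large family of reductases and lies among the aromatic degradation genes. The tricarboxylic acid and glyoxylate cycle genes had a median of 0.42 over 18 genes (percentile 99.85), yet 0 passed the 2-fold rule in either direction. The fumarase gene fumC had a log2 ratio of 0.74. The member acnD had one of -0.95 and lies near the 2-methylisocitrate lyase gene prpB (0.93) in locus-tag order. Both may serve another pathway than these cycles.

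**Figure D2:**
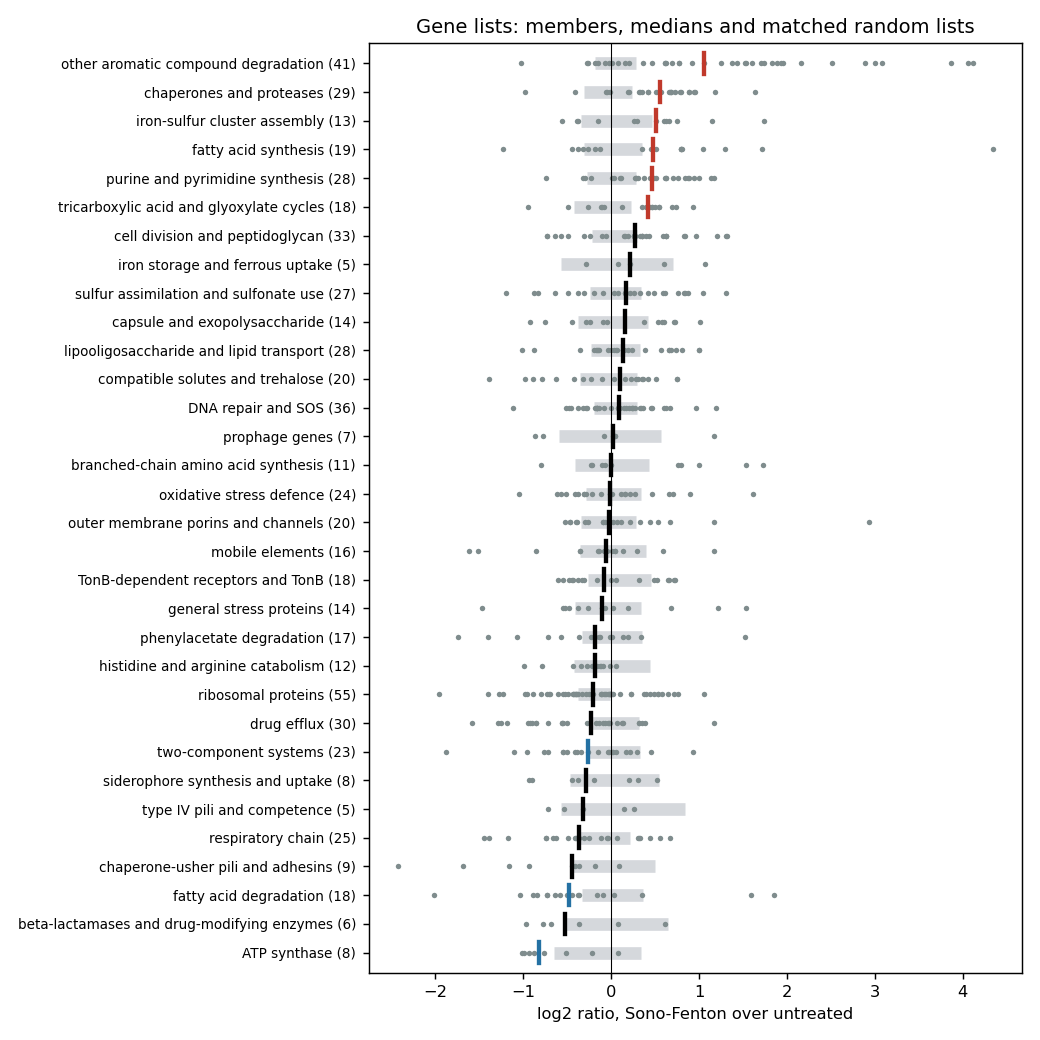
Each grey point is a gene of the list named on the y axis (number of measured genes in brackets), placed by its log2 ratio of Sono-Fenton over untreated. Vertical bars are list medians, red or blue where above or below the central 95% of matched random medians (pale band), and among these lists of at least 5 genes aromatic compound degradation has the highest median at 1.06 and ATP synthase the lowest at -0.82.

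Genes past the rule often lay side by side in locus-tag order. Runs of at least 4 neighbouring genes past it in the same direction held 58 higher and 30 lower genes, in 8 and 6 runs. These are the runs under TMM scaling, and they were not counted under total-count scaling, which added 0.17 to every log2 ratio. That shift takes lptE (-0.84) out of its run. It also breaks the lower run from CAHBGAOC_02255 to CAHBGAOC_02258, where the ratio nearest to 0 was -1.07. The longest, of 11 genes from ftsB to pcaG, included pcaI_1, pcaJ_1, pcaF_1, pcaH and pcaG of the protocatechuate pathway, with log2 ratios from 1.22 to 1.96.

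**Figure D3:**
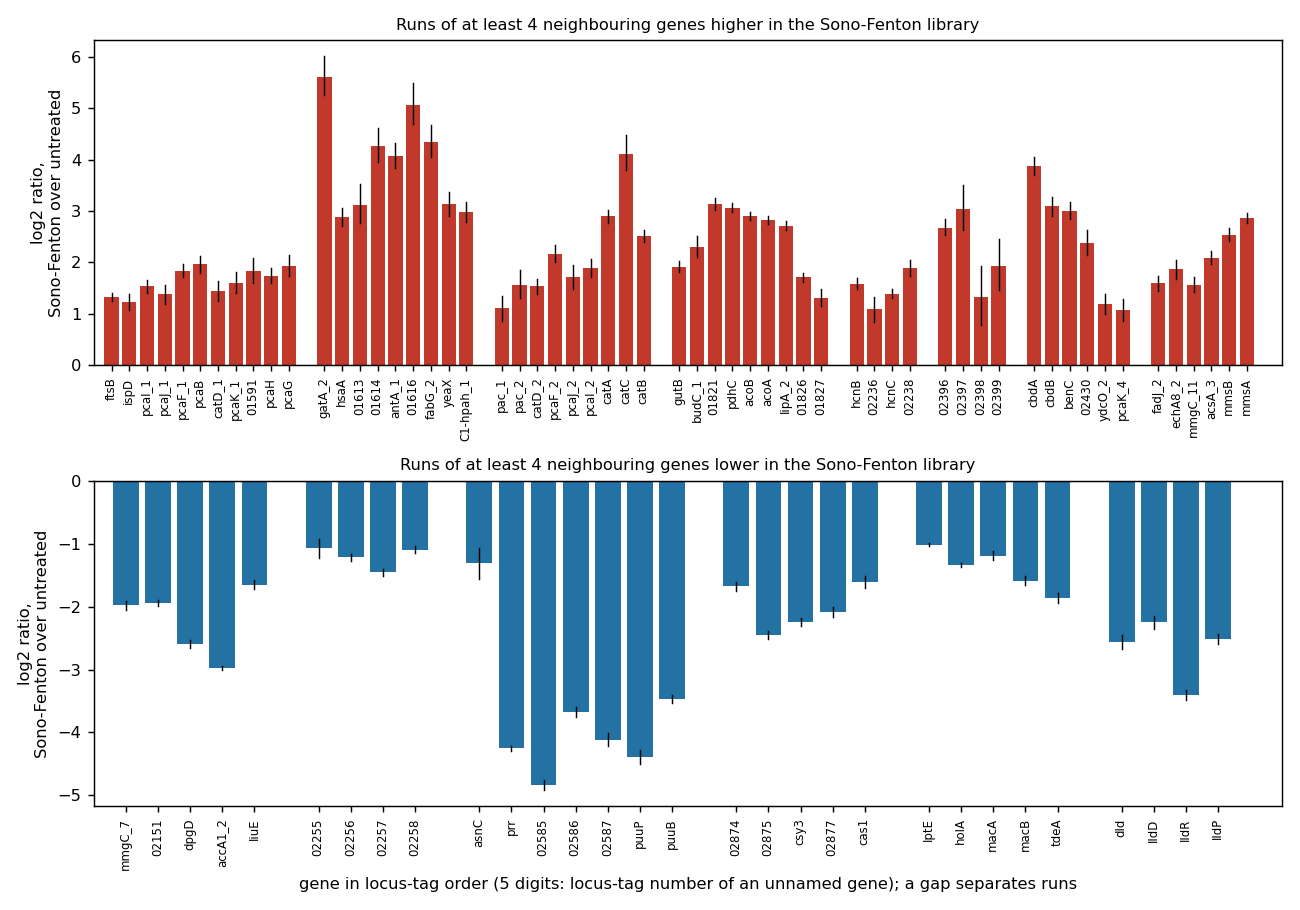
Bars are log2 ratios of Sono-Fenton over untreated (y axis) for genes in locus-tag order (x axis) in the runs of at least 4 neighbouring genes that all passed the 2-fold rule in the same direction, with 95% counting intervals as lines. The upper panel holds 8 higher runs (58 genes) and the lower panel 6 lower runs (30 genes).

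Genes that remove oxidants did not differ as a group. Of 24 oxidative stress defence genes, 1 was higher and 1 was lower, with a median log2 ratio of -0.01 (percentile 38.6). The catalase gene katE (CAHBGAOC_02134) was 3.05-fold higher (2.98 to 3.13). The catalase-peroxidase gene katG had a log2 ratio of -0.41, the alkyl hydroperoxide reductase gene ahpC -0.31, the iron superoxide dismutase gene sodB -0.28, and the peroxide sensor gene oxyR 0.16. The ahpF copies had log2 ratios of 0.11 (interval including 0) and 0.27, and the glutaredoxin gene grxD 0.90. The lower member was soxR_1, a redox-sensing regulator with only 44 and 28 counts, at 2.06-fold (1.26 to 3.46), and its neighbouring copy soxR_2 had a log2 ratio of -0.61. In the list of chaperones and proteases, 2 of 29 genes were higher and 0 lower, with a median of 0.56 (percentile 100). The co-chaperone gene dnaJ was 3.10-fold higher and the heat shock gene hslR 2.27-fold higher. The protease gene lon_1 had a log2 ratio of -0.98, and the chaperone genes groL, clpB and dnaK had 0.19, -0.05 and -0.01. DNA repair and SOS genes had 1 of 36 higher (recR, 2.28-fold) and 1 lower (umuC_2, 2.17-fold), with a median of 0.09 (percentile 64.1). The recombinase gene recA had a log2 ratio of -0.16. General stress proteins had 2 of 14 higher and 1 lower, with a median of -0.10 (percentile 35.8). The universal stress protein gene CAHBGAOC_01419 was 2.91-fold higher, and hfq, whose product binds small RNAs, was 2.76-fold lower.

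Of the genes on the lists for iron uptake and storage, 1 passed the 2-fold rule, and it is a regulator. The ferric uptake regulator gene fur was 2.10-fold higher (1.94 to 2.29), the 1 higher gene among 5 of iron storage and ferrous uptake, whose median was 0.21 (percentile 73.3). The bacterioferritin copies bfr_1 and bfr_2 had log2 ratios of 0.21 and 0.07, and the ferrous iron transporter gene feoB 0.60. Of 8 siderophore genes 0 passed the rule, with a median of -0.28 (percentile 12.8) and entC at -0.94. Of 18 genes for TonB-dependent receptors and the TonB system 0 passed it, with a median of -0.08 (percentile 16.7) and iutA_2 at 0.72. Iron-sulfur cluster assembly had 2 of 13 genes higher and 0 lower, with a median of 0.51 (percentile 98.3), a position not kept when the list was shifted along the gene order (percentile 95.9). The insertion protein gene erpA was 3.35-fold higher and the ferredoxin gene fdx_1 2.22-fold higher. The log2 counts of the 7 neighbouring genes from iscR_2 to fdx_1 had an SD of 1.44 in the untreated and 1.06 in the treated library.

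Several envelope and transport genes had lower levels in the treated library. Among chaperone-usher pili, which are surface fibres for attachment, 3 of 9 genes were lower and 0 higher, with a median of -0.44 (percentile 3.36). This percentile was past the bound without removals by name (1.13). It was not among unmatched lists (3.625), with at least 100 counts (3.86) or among circular shifts (6.15). The usher gene htrE_1 was 5.35-fold lower (5.25 to 5.46), the chaperone gene yadV_1 beside it 3.21-fold lower and the adhesin gene mrkD_1 2.23-fold lower. Among 30 drug efflux genes 4 were lower and 1 was higher, with a median of -0.22 (percentile 3.10). Their percentile was past the bound by symbol alone (1.32), with at least 100 counts (1.46) and without removals by name (2). It was not among unmatched lists (4.66) or circular shifts (5.18). The macrolide export genes macB and macA had log2 ratios of -1.59 and -1.19, and the pump gene mexB_1 was 2.39-fold lower, with 119010 counts against 65614. Of 6 beta-lactamase and drug-modifying enzyme genes 0 passed the rule, with a median of -0.52 (percentile 2.95), and ampC had a log2 ratio of -0.96. Among 20 porins and outer membrane channels 2 were higher, nicP_1 (7.65-fold) and tolC (2.26-fold), and the median was -0.02 (percentile 54.6) but the mean 0.17. The main outer membrane protein Omp38 (CAHBGAOC_00604), also known as OmpA, had a log2 ratio of -0.53 with 278931 and 254993 counts. Capsule and exopolysaccharide genes had 1 of 14 higher and 0 lower, with a median of 0.16 (percentile 74.6). The higher gene was pgaA, for export of the poly-N-acetylglucosamine matrix, at 2.02-fold. Lipooligosaccharide and lipid transport genes had 1 of 28 higher (kdsC, 2.01-fold) and 1 lower (lptE, 2.01-fold), with a median of 0.13 (percentile 73.9). Type IV pili genes had 0 of 5 past the rule, a median of -0.32 (percentile 10.8) and pilQ at -0.72.

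Genes of energy conversion were lower in part. The 8 ATP synthase genes had a median of -0.82 (percentile 0.77). Of these 1 passed the rule, atpC at 2.02-fold lower, with atpA at a log2 ratio of -0.93. Of 25 respiratory chain genes 3 were lower and 0 higher, with a median of -0.37 (percentile 3.10). The percentile was past the bound among unmatched lists (0.875), but not with at least 100 counts (3.25) or among circular shifts (3.49). The genes cyoE, nuoG and nuoM were 2.72-fold, 2.62-fold and 2.26-fold lower. Ribosomal protein genes had 4 of 55 lower and 1 higher and a median of -0.21. Their percentile was 38.95 among matched lists, 1.68 among unmatched lists and 5.21 among circular shifts. The gene rpsQ was 3.89-fold lower (3.86 to 3.91) and rplQ 2.64-fold lower. In 6 of the 7 blocks of at least 4 neighbouring genes from these lists log2 counts were less even in the untreated library. Their SD was 1.79 against 1.38 over the 12 genes from nuoN to nuoB, 1.37 against 0.889 over the 21 from rpsJ to rplO, and 1.10 against 0.867 over the ATP synthase genes. The exception was the block of 5 genes from cyoE to cyoA, at 1.58 against 1.67. The difference was small over the 4 genes from rpmJ to rpsD, where the SD of the treated minus that of the untreated library was -0.0166. Reference genes often taken as stable had log2 ratios of 0.90 (rpoD), 0.56 (gyrB) and 0.06 (gyrA).

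Nucleotide synthesis genes were shifted the other way. Purine and pyrimidine synthesis had 3 of 28 genes higher and 0 lower, with a median of 0.47 (percentile 99.9). The uridylate kinase gene pyrH was 2.26-fold higher and purK_1 2.21-fold higher. Cell division and peptidoglycan genes had 3 of 33 higher and 0 lower, with a median of 0.28 (percentile 96.4). These were ftsB, ftsA_1 and murG, with log2 ratios of 1.32, 1.31 and 1.20. Of these, ftsB is the first gene of the run of 11 higher genes that ends at pcaG. Two-component systems had 2 of 23 genes lower and 0 higher, with a median of -0.27 at the very bound (percentile 2.5). It lay inside the bound in each of the 4 alternatives, at 2.55 with at least 100 counts, 4.13 among unmatched lists, 5.46 among circular shifts and 18.8 with members by symbol alone. The nitrogen regulator gene glnG was 3.69-fold lower (3.64 to 3.74).

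The remaining lists lay within the central 95%. Branched-chain amino acid synthesis had 2 of 11 genes higher, the leucine pathway genes leuD (3.30-fold) and leuC (2.89-fold), with a median of -0.01 (percentile 49.4) and a mean of 0.40. Sulfur assimilation had 2 of 27 higher and 1 lower, with a median of 0.17 (percentile 79.6) and ssuD_1 2.48-fold higher. Histidine and arginine catabolism had 0 of 12 past the rule, a median of -0.19 (percentile 17.3) and astC_2 at -0.99. Compatible solute genes had 1 of 20 lower (betI_1, 2.62-fold), with a median of 0.10 (percentile 78.7) and a mean of -0.08. Of 16 mobile element genes 1 was higher and 2 were lower, with a median of -0.06 (percentile 35.6). The lower genes are copies of the ISAba11 transposase, 3.08-fold and 2.85-fold lower, whose reads cannot be assigned with certainty. Prophage genes had 1 of 7 higher (intA_2, 2.24-fold), a median of 0.02 (percentile 55.9) and a mean of -0.06. The mean also had the other sign than the median for oxidative stress defence and TonB-dependent receptors (0.02 for each). Among 3 toxin-antitoxin genes, too few for a percentile, the neighbours higB-2 and higA-2 were 2.81-fold and 2.37-fold higher. The quorum sensing list held 1 gene, anoI, with 93 and 123 counts and an interval including 0, and the type VI secretion list matched 0 genes.

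In all, 9 of 32 lists lay outside the central 95%, 6 high and 3 low. If the members of each list were independent draws of genes, 1.6 would be expected. Members that lie side by side are not independent, so the 2 numbers are not a test. Of the 9 lists, 7 stayed outside in every list alternative tried. The exceptions were iron-sulfur cluster assembly and two-component systems. All ratios compare 2 libraries and not the conditions, since neither group has a second library.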

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

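The circular shifts and the lists without removals by name were chosen after seeing the data, and the other alternatives before. With total-count scaling 456 genes were higher instead of 299, because every log2 ratio moved by 0.17. With a log2 ratio of at least 2 the counts were 50 higher and 33 lower, since the rule is stricter. DESeq2 size factors (294 higher, 244 lower), both other count minimums and a whole interval beyond 2-fold left the counts within 1.5 times. Of 166 named genes 86 were past the 2-fold rule. Of these 78 stayed past it with total-count scaling, which took 8 lower genes within it (log2 ratios from -0.84 for lptE to -0.99 for mrkD_1), and 85 with DESeq2 size factors (all but kdsC). Total-count scaling moved 136 of the 166 by more than their counting interval. Iron-sulfur cluster assembly had percentile 95.9 under circular shifts. Two-component systems had 4.13 with unmatched lists, 18.8 by symbol alone, 2.55 with at least 100 counts and 5.46 under circular shifts. Lists that passed a bound only in an alternative were drug efflux (1.32 by symbol alone, 1.46 with at least 100 counts, 2 without removals by name), capsule (97.8 by symbol alone), chaperone-usher pili (1.13 without removals), ribosomal proteins (1.68 unmatched), respiratory chain (0.875 unmatched) and cell division (97.6 unmatched). For these lists the cause was not tested. Keeping ribosomal RNA in the library size gave no value, as the tables hold no such rows. Depth limited few genes, since 46 of the 3725 genes kept had under 100 summed counts, and the missing second library limits every ratio.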

Other observations

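The genes in this part were chosen after their values were seen, and so were the tests of chance placement, counting error in runs, shared copies and growth rate. The bounds of the shared copies and growth rate tests were also changed after their values were seen. Beyond the fixed lists, whole stretches of neighbouring genes differed together. From gutB to CAHBGAOC_01827, 9 genes were higher, among them acoA and acoB, names used for acetoin dehydrogenase subunits, and the lipoyl synthase gene lipA_2, with a median log2 ratio of 2.70. From fadJ_2 to mmsA, 6 genes were higher with a median of 1.97, and mmsA and mmsB are names of valine catabolism. From hcnB to the hydroxyproline epimerase gene CAHBGAOC_02238, 4 genes were higher with a median of 1.49. Lower stretches included 7 genes from asnC to puuB (median -4.11), 5 genes from mmgC_7 to liuE (median -1.97), 4 lactate genes from dld to lldP (median -2.53) and 5 genes from lptE to tdeA (median -1.33). A further 5 lower genes end at cas1 and include csy3, both CRISPR-associated (median -2.08).

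Near the catalase gene katE lie hypothetical proteins with large differences in counts. CAHBGAOC_02137 had 12521 counts in the untreated and 139173 in the treated library (log2 ratio 3.07), and CAHBGAOC_02138 had 1376 and 32703 (log2 ratio 4.17). In the same stretch, CAHBGAOC_02131 had a log2 ratio of 3.32, CAHBGAOC_02135 one of 1.08, CAHBGAOC_02139 one of 1.38 and the general stress gene ydaD one of 1.22. CAHBGAOC_02132 between them had -0.57. No run of at least 4 neighbouring genes past the 2-fold rule lay in this stretch, so it was not higher throughout.

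The first pattern weighed is that genes past the 2-fold rule lie side by side. Runs of at least 4 neighbouring genes past it in the same direction held 88 genes in 14 runs. In 1000 shuffles of the calls at most 12 genes lay in such runs. Placement of calls independently of their neighbours is thus argued against, and nothing further follows. Log2 ratios of neighbours correlated at Spearman 0.347 across 3682 pairs of genes, so any difference between the cultures could give such runs. Of all 3725 genes, 0.24% (9) had a counting interval that reached 1 (log2) to either side, while 14.5% were past the rule. The rule already asks for an interval that excludes 0, and this share does not single out run genes. It is therefore no separate test of counting error in the runs. Reads shared between gene copies stay open, since a copy number in a name does not measure sequence identity. A gene with such a number is found in 7 of the 14 runs (50%), and 2 more hold only genes without a symbol. Of 63 named run genes 25 carry such a number, 23 of them in higher runs. No share over all genes is given here, so these counts do not bear on the question. Sono-Fenton stays open beside any other difference between the single cultures.

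The second pattern is that catabolic gene clusters differ in opposite directions, such as that from pac_1 to catB (9 genes higher) and those from asnC to puuB and from dld to lldP (7 and 4 genes lower), though of these directions only that of aromatic compound genes was covered by a fixed list, and phenylacetate genes did not share it. A candidate explanation is that the cultures were collected at different points of growth in nutrient broth, where bacteria use up amino acids and amines in turn. Ribosomal protein genes, which follow growth rate, were at percentile 38.95 among matched lists but 1.68 among unmatched lists and 5.21 among circular shifts. The central 95% of the matched random medians ran from -0.37 to -0.01, so genes of similar mean level tended to be lower too. Matched and unmatched percentiles therefore answer different questions. They disagree and the labels give no cell density, so a growth difference and the treatment cannot be told apart here. Ribosomal protein genes themselves are an expected 17.2% of a matched list and 1.48% of an unmatched one.

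The third pattern is that counts of neighbouring genes of one list were less even in the untreated library. In 16 of 21 blocks (76.2%), 6 of them ribosomal, ATP synthase or respiratory, the SD of log2 counts was smaller in the treated library, with a median SD of 1.23 in the untreated and 0.999 in the treated library. Counting error is argued against, since its median over blocks of 0.0474 lies below the median SD difference of -0.14 in size. Less even recovery of reads in the untreated library as a whole would also show outside the blocks, where 447 of 875 windows of 4 neighbouring genes (51.1%) had the smaller SD in the treated library. That is close to an even split but above the 50% set as the bound against it, and windows can span several transcripts, so uneven recovery stays open, as does separate regulation within the blocks after Sono-Fenton, which was not tested.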
